A study of Homo sapiens with 6 samples.

How the data were processed

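RNA sequencing values of 6 libraries were used, 3 of vehicle-treated and 3 of halofuginone-treated human cardiac fibroblasts of the ventricle. Per the labels' protocols, cells at passage 5 received 200 nM halofuginone for 24 h, RNA was taken with Trizol, and libraries were made with the TruSeq RNA Sample Prep kit. The deposited values are FPKM, per the file headers, with 1 column per library and 1 row per RefSeq transcript and locus. Per the submitters' processing notes bcl2fastq was used. The aligner, the program that assigned reads to transcripts, the genome build and the annotation release are not given in the sources used here, so no coordinates are printed. The labels do not state whether strand was kept, so reads of overlapping or antisense genes cannot be told apart. The table's control columns were taken as the vehicle samples of the same number.

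The table held 36004 transcript rows with 22300 gene names, and 864 rows were further loci of a transcript already listed. Rows on the Y chromosome and those of XIST and TSIX were left out before any step, which left 35738 rows of 22198 genes. Of these genes, 15095 had 1 transcript and 7103 had 2 or more. FPKM were summed over the transcripts of a gene. The plan written before the data were examined kept rows as given, with the sum as the alternative. The 2 were exchanged before any test, when the table was seen to hold transcripts, and the rows as given became an alternative. Of 982 list genes 969 were matched by symbol or an older symbol. The 13 others were the transcripts of the mitochondrial genome, a list not analysed here.

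Depth was estimated from the low values. In genes with 1 transcript and below 0.3 FPKM in each library, a value from whole reads is a multiple of what 1 read is worth. Ratios of such values gave the worth of 1 read relative to vehicle replicate 1. It was 1.37 and 1.24 for vehicle replicates 2 and 3, and 1.29, 1.01 and 1.13 for halofuginone replicates 1 to 3. Total depth came from 3003 genes with 1 transcript, a higher limit on FPKM and a GENCODE 29 transcript length matched by RefSeq accession. Such lengths cover 96.8% of the FPKM. At the best depth 57.1% of the low values of these genes were within 0.05 of a whole read. Among depths below 0.8 of it the median was 7.1% and the highest 25.9%. Total depth is therefore an estimate, and no test of reads was run. Replicates were compared on estimated reads. A chi-square per gene, where 1 stands for sampling noise, was 1.35 to 2.09 between replicates and 36.1 to 41.4 between groups for genes of 50 to 500 reads. Between replicates it was 1.2 to 1.34 for genes of 10 to 50 reads and 1.96 to 5.82 for 500 to 5000. Replicates thus differed by more than sampling noise, and no 2 libraries were counted as 1. These values do not tell separate cultures from technical repeats.

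The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), with an intensity trend, for genes with a mean of at least 1 FPKM over the 6 libraries and group as the only term. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes of this fit are on the log2(FPKM + 0.5) scale, which understates the change of low genes. Counts of genes by fold, such as those changed at least 2-fold or less than 1.5-fold, use this scale. Folds printed as "-fold" for a single named gene are ratios of mean FPKM. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, over the 34 lists with at least 3 tested members of the 39 fixed before the data were examined (27 of them pathways). Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The procedure was tested on simulated data with the means and spreads of these 11714 genes. Of 50 genes changed 1.25-fold, 88% were recovered, and of 50 genes each changed 1.5-fold, 2-fold and 4-fold, 100% were. Besides these, 18 unchanged genes were called. Only the genes counted here were changed, while 84.0% of the tested genes were called in the data. The simulated noise was independent between genes, with no shift of scale and no GC trend, so errors from these were not tested.

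The genes named were chosen by a rule fixed before the data were examined. It takes the 12 largest rises and 12 largest falls among called genes whose groups do not overlap and whose higher group mean is at least 5 FPKM. From each pathway list it takes up to 3 called members with the largest change and the uncalled member with the highest mean. A fixed set is always named, namely EPRS, ATF4, DDIT3, ASNS, COL1A1, COL1A2, COL3A1, ACTA2, TGFB1, CDKN1A, MKI67, FN1, POSTN, GAPDH and ACTB. Of the genes that the rule selects, 3 are not reported here, and no other gene takes their place. Alternatives planned before the data were examined were pseudocounts of 0.1 and 1, no filter and a filter at 5 FPKM, median-ratio scaling, scaling to the same sum, quantile normalization, the replicate number as a block, limma with a robust prior, without the trend and without variance moderation, an adjusted p below 0.01, and leaving out each library. Transcript rows as given, a test against a 2-fold change (treat) and median-ratio scaling together with the removal of trends on GC content and transcript length were added after the table was seen.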

Results

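Gene expression was measured by RNA sequencing in primary human cardiac fibroblasts of the ventricle, the cells that make and remodel the matrix of the heart wall. Cells at passage 5 received vehicle or 200 nM halofuginone for 24 h, with 3 libraries per group. Halofuginone, a derivative of the plant alkaloid febrifugine, blocks the prolyl site of EPRS, the enzyme that loads glutamate and proline onto their tRNAs. The comparison asks which transcripts differ after a day of the drug. The estimated depth was 35600000, 26100000 and 28800000 fragments for vehicle replicates 1 to 3 and 27600000, 35200000 and 31600000 for halofuginone replicates 1 to 3. At these depths, 1 FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of a library) on a transcript of 2 kb stood for 52 to 71 reads. Between 11551 and 11690 genes reached 1 FPKM in a library. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

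Targets of the integrated stress response rose under halofuginone, and transcripts of the contractile apparatus and the extracellular matrix fell. These calls of gene lists ended with an estimated correlation (adjusted p = 0.195 for the stress response, 0.246 for contractile genes, 0.419 for collagens and 0.246 for other matrix genes). IGFBP1, a secreted binder of insulin-like growth factors, went from 0.830 ± 0.103 to 58.4 ± 2.27 FPKM (mean ± SD, n = 3 libraries here and below, vehicle to halofuginone), the largest rise on the log2 scale. TRIB3, a pseudokinase induced by CHOP, went from 6.02 ± 0.501 to 160.1 ± 0.231 FPKM. DDIT3, which encodes CHOP itself, rose from 21.7 ± 0.647 to 281 ± 10.8 FPKM, and GDF15, a stress-induced cytokine, from 21.8 ± 2.91 to 301 ± 5.39 FPKM. FGF2, a fibroblast growth factor, rose 16.9-fold, from 16.4 ± 0.854 to 278 ± 13.3 FPKM. The cytokine genes IL6 and IL1A rose from 11.2 ± 1.60 to 148 ± 4.17 and from 0.440 ± 0.0789 to 19.8 ± 2.37 FPKM. CD274, which encodes the immune checkpoint ligand PD-L1, rose from 0.444 ± 0.0418 to 13.5 ± 0.862 FPKM, and LAMP3, a lysosomal membrane protein, from 0.186 ± 0.0490 to 9.96 ± 0.595 FPKM. BEX2 rose from 0.235 ± 0.0423 to 17.6 ± 0.599 FPKM and DHRS2, a short-chain dehydrogenase, from 0.0937 ± 0.0796 to 10.8 ± 2.82 FPKM. IL24, a cytokine of the IL-10 family, was listed at 0 in each vehicle library and at 5.80, 7.91 and 5.97 FPKM in halofuginone replicates 1 to 3.

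The largest fall was that of INMT, a methyltransferase of indoleamines, from 55.7 ± 1.36 to 0.625 ± 0.139 FPKM. CD14, a co-receptor for bacterial lipopolysaccharide, fell from 35.4 ± 0.724 to 1.38 ± 0.246 FPKM, and LMOD1, an actin nucleator of smooth muscle, from 31.8 ± 0.547 to 1.42 ± 0.0748 FPKM. MRVI1, a substrate of cGMP-dependent kinase, fell from 35.8 ± 1.05 to 2.18 ± 0.334 FPKM. SLC40A1, the iron exporter ferroportin, fell from 31.7 ± 0.376 to 2.03 ± 0.137 FPKM, and SLC6A6, the taurine transporter, from 46.9 ± 0.660 to 4.34 ± 0.303 FPKM. SELENBP1 fell from 20.3 ± 0.824 to 1.22 ± 0.0392 FPKM, CLIC3 from 13.8 ± 1.68 to 0.898 ± 0.175 FPKM, STARD5 from 23.3 ± 0.331 to 2.02 ± 0.0443 FPKM and OLFML3 from 21.9 ± 1.33 to 1.91 ± 0.314 FPKM. PMCH, which encodes a neuropeptide precursor, fell from 5.57 ± 0.549 to 0.0919 ± 0.0158 FPKM, and the uncharacterised LOC730101 from 22.5 ± 0.502 to 1.28 ± 0.172 FPKM.

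Of 11714 genes tested with limma, 5664 were higher and 4178 lower in halofuginone at an adjusted p below 0.05, and 1872 were not called. Among these, 977 were higher and 823 lower by at least 2-fold, and 55.6% of the called genes changed by less than 1.5-fold. Which direction held more of the 2-fold changes rests on the scaling: 825 were higher and 948 lower under median-ratio scaling, and 818 and 955 under quantile normalization. The values of the groups did not overlap for 84.8% of the genes, where chance gives 10% for 3 libraries against 3. The median SD within a group was 0.06 on the log2 scale. Adjusted p-values of the 107 called genes among the 128 named by rule lay between 1.27e-15 and 3.29e-06. Of 34 gene lists fixed before the data were examined, camera with a preset inter-gene correlation of 0.01 called 16, of which 6 were higher and 10 lower than the other genes. With an estimated correlation camera called 0 lists, with 6 at an unadjusted p below 0.05 and adjusted p-values from 0.195 to 0.979. The correlation is estimated from the spread within groups of 3 libraries, so this form of the test can miss lists that differ. Its lack of calls decides neither way. The rotation test fry, which asks whether a list's genes moved without comparing them with other genes, called 33. The counts adjusted over the list alone were the same as those over all genes tested, apart from the 5 lists where both are given.

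**Figure D1:**
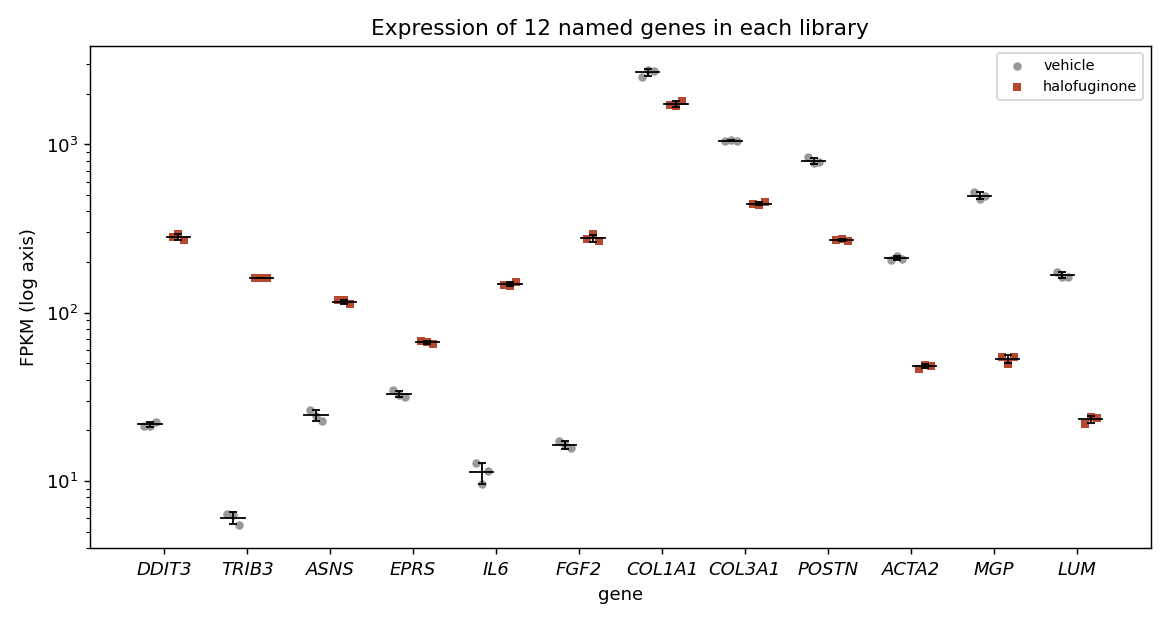
Expression of 12 named genes in each library, in FPKM on a log axis, with grey circles for the 3 vehicle libraries and red squares for the 3 halofuginone libraries, horizontal lines for group means and bars for the SD. The 3 values of one group lie apart from those of the other for each gene plotted, from 6.02 ± 0.501 to 160.1 ± 0.231 FPKM for TRIB3 to 167 ± 7.01 to 23.2 ± 1.11 FPKM for LUM.

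Among 25 tested targets of ATF4 and CHOP, the transcription factors of the integrated stress response, 24 were higher and 1 lower, and 20 rose by at least 2-fold (camera adjusted p = 4.24e-08; adjusted p = 0.195 with an estimated correlation). Their median log2 change was 1.77. On the log2 scale TRIB3 rose by 4.63 ± 0.050 (SE), GDF15 rose by 3.77 ± 0.071 (SE) and DDIT3 rose by 3.67 ± 0.038 (SE). ASNS, asparagine synthetase, rose 4.75-fold, from 24.5 ± 1.76 to 116 ± 3.29 FPKM, while the transcript of ATF4 rose 1.21-fold, from 245 ± 6.34 to 297 ± 0.882 FPKM. EPRS, the enzyme that halofuginone inhibits, rose 2.03-fold, from 32.9 ± 1.55 to 66.7 ± 1.16 FPKM (limma adjusted p = 4.75e-11).

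Cytosolic aminoacyl-tRNA synthetases rose as a list, with 15 of 21 higher, 2 lower and 4 not called (camera adjusted p = 0.00366; adjusted p = 0.371 with an estimated correlation). Adjusted over the list alone, 15 were higher and 1 lower. WARS, for tryptophan, rose from 58.0 ± 1.71 to 457 ± 7.89 FPKM, GARS, for glycine, from 82.8 ± 1.44 to 259 ± 1.57 FPKM and IARS, for isoleucine, from 43.5 ± 1.61 to 131 ± 2.64 FPKM. KARS, for lysine, was not called, at 46.4 ± 0.790 and 48.0 ± 0.432 FPKM in vehicle and halofuginone (adjusted p = 0.188). Of 17 mitochondrial synthetases, 5 were higher, 9 lower and 3 not called, and the list was not called (camera adjusted p = 0.277). SARS2 fell from 6.25 ± 0.454 to 1.255 ± 0.153 FPKM, FARS2 from 4.53 ± 0.196 to 2.11 ± 0.0794 FPKM and LARS2 from 4.82 ± 0.228 to 2.44 ± 0.0745 FPKM. CARS2 was not called, at 15.4 ± 0.550 and 16.3 ± 0.541 FPKM. Plasma membrane amino acid transporters rose, with 11 of 16 higher, 3 lower and 2 not called (camera adjusted p = 0.0119; adjusted p = 0.246 with an estimated correlation). SLC7A1, for cationic amino acids, rose 8.12-fold, from 5.85 ± 0.137 to 47.5 ± 0.745 FPKM. SLC7A11 and SLC3A2, the subunits of the cystine-glutamate exchanger, rose from 10.3 ± 0.751 to 63.2 ± 0.632 and from 83.0 ± 2.68 to 471 ± 7.89 FPKM. SLC7A6 was not called, at 7.66 ± 0.135 and 7.92 ± 0.265 FPKM.

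Genes of serine synthesis and one-carbon folate metabolism were not called as a list, with 8 of 10 higher and 2 lower (camera adjusted p = 0.113). The list was called higher on transcript rows (adjusted p = 0.0354) and after median-ratio scaling and removal of GC content and length trends (adjusted p = 0.0445). With an estimated correlation in the main fit, camera gave it an adjusted p = 0.385. MTHFD2, a mitochondrial folate enzyme, rose from 47.1 ± 2.34 to 180.3 ± 1.85 FPKM, PSAT1 from 43.5 ± 1.76 to 141 ± 4.30 FPKM and SHMT2 from 57.5 ± 1.86 to 146 ± 2.54 FPKM. Of 15 genes of proline, asparagine, glutamate and glutamine metabolism, 6 were higher, 5 lower and 4 not called (camera adjusted p = 0.979). The median of this list was -0.07 and its mean 0.34, so the 2 differed in sign. GOT1, an aspartate aminotransferase, rose from 10.97 ± 0.3003 to 89.2 ± 1.09 FPKM, and ASS1, of arginine synthesis, fell from 21.1 ± 1.13 to 8.45 ± 0.380 FPKM.

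Collagen transcripts fell. Of 24 collagen chains tested, 18 were lower, 4 higher and 2 not called, with a median log2 change of -0.36 (camera adjusted p = 3.31e-04, and 0.419 with an estimated correlation). After median-ratio scaling and removal of GC content and length trends the median was -0.16 (camera adjusted p = 0.0377). COL1A1 and COL1A2, the chains of type I collagen, fell from 2683 ± 136 to 1743 ± 66.9 and from 2557 ± 47.2 to 1354 ± 39.3 FPKM, and COL3A1 fell 2.36-fold, from 1052 ± 5.93 to 445 ± 10.6 FPKM. COL27A1 fell from 3.22 ± 0.315 to 0.905 ± 0.0259 FPKM and COL14A1 from 3.48 ± 0.371 to 1.26 ± 0.135 FPKM. COL4A5 was not called, at 16.3 ± 0.315 and 15.7 ± 0.409 FPKM. Of 31 genes for collagen hydroxylation, folding, cleavage and crosslinking, 27 were lower and 4 higher (camera adjusted p = 1.33e-06; adjusted p = 0.262 with an estimated correlation). PCOLCE, which enhances procollagen cleavage, fell from 69.3 ± 4.16 to 13.99 ± 0.929 FPKM. SERPINH1, the collagen chaperone HSP47, fell from 316 ± 10.6 to 102 ± 4.73 FPKM, and ADAMTS14, a procollagen protease, from 11.9 ± 0.671 to 3.56 ± 0.186 FPKM.

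Other matrix genes fell as well, with 39 of 44 lower, 4 higher and 1 not called (camera adjusted p = 3.38e-09; adjusted p = 0.246 with an estimated correlation). MGP, an inhibitor of calcification, fell 9.31-fold, from 495 ± 24.5 to 53.2 ± 2.88 FPKM, and LUM, the proteoglycan lumican, from 167 ± 7.01 to 23.2 ± 1.11 FPKM. EMILIN1, an elastic fibre protein, fell from 70.0 ± 4.27 to 17.3 ± 1.26 FPKM and POSTN, periostin, from 799 ± 37.0 to 270.0 ± 2.95 FPKM. FN1, fibronectin, the most abundant of the named genes, fell from 5894 ± 228 to 3988 ± 104 FPKM. This call ended under quantile normalization, which gives the top-ranked gene the same value in each library. ASPN was not called, at 5.57 ± 0.503 and 5.22 ± 0.175 FPKM. Matrix metalloproteinases and their inhibitors were listed with the plasminogen activators PLAU and PLAT and the receptor PLAUR. This list was not called, with 5 of 17 higher, 10 lower and 2 not called (camera adjusted p = 0.0837). MMP11 fell from 11.2 ± 0.274 to 2.64 ± 0.457 FPKM and RECK, a membrane inhibitor of these proteases, from 81.2 ± 3.67 to 28.4 ± 0.239 FPKM, while MMP1, an interstitial collagenase, rose from 62.7 ± 4.41 to 142 ± 6.74 FPKM. PLAUR was not called, at 26.8 ± 0.741 and 27.1 ± 1.17 FPKM.

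Contractile genes of activated fibroblasts had the lowest median of the pathway lists, -1.13 on the log2 scale. Of 20 tested, 18 were lower, 12 of them by at least 2-fold, 1 was higher and 1 not called (camera adjusted p = 1.00e-07; adjusted p = 0.246 with an estimated correlation). ACTA2, smooth muscle actin, fell 4.40-fold, from 211 ± 6.52 to 48.0 ± 1.38 FPKM, and TNS1, a focal adhesion protein, from 69.5 ± 1.89 to 17.1 ± 1.13 FPKM. LMOD1 fell by 4.08 ± 0.049 (SE). TPM1, a tropomyosin, was not called as a sum over its transcripts, at 612 ± 7.70 and 628 ± 10.1 FPKM. ACTB and GAPDH, often used as reference genes, both fell, ACTB 3.45-fold, from 1629 ± 35.7 to 472 ± 9.30 FPKM, and GAPDH 1.37-fold, from 2756 ± 117 to 2011 ± 25.3 FPKM. Actins, GAPDH and ribosomal protein genes have many near-identical copies, so their levels are uncertain where the authors' assignment of reads could split them.

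Genes of TGF-beta signalling went both ways, with 13 of 25 higher, 11 lower and 1 not called (camera adjusted p = 0.843). Their median of 0.07 was above 0 while camera placed the list lower than other genes, without a call. TGFB2 rose 5.66-fold, from 17.6 ± 0.587 to 99.8 ± 1.71 FPKM. TGFB3 fell 6.45-fold, from 4.35 ± 0.231 to 0.673 ± 0.0199 FPKM, and TGFB1 1.40-fold, from 67.5 ± 5.79 to 48.2 ± 2.45 FPKM. TGIF1, a repressor of SMAD signalling, rose from 20.7 ± 0.675 to 82.5 ± 1.90 FPKM. SKI was not called, at 25.2 ± 0.905 and 26.4 ± 0.626 FPKM.

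Cytokines, chemokines and NF-kappaB targets had 14 of 22 members higher and 8 lower, 12 of them higher and 2 lower by at least 2-fold, and the list was not called (camera adjusted p = 0.135). IL8, a neutrophil chemokine, rose from 1.92 ± 0.319 to 27.4 ± 2.19 FPKM. Tested immediate early genes rose, with 13 of 15 higher, 1 lower and 1 not called (camera adjusted p = 7.69e-04, and 0.419 with an estimated correlation). The other members, FOS, FOSB, EGR2 and EGR3, were below the filter, untested and lower in halofuginone. FOS went from 1.18 to 0.475 FPKM, FOSB from 0.426 to 0.217, EGR2 from 1.03 to 0.618 and EGR3 from 0.594 to 0.0874. They lie outside the rule for named genes and were added after their values were seen. DUSP6, a phosphatase of ERK, rose from 2.67 ± 0.240 to 17.1 ± 0.356 FPKM, MYC from 26.4 ± 1.11 to 125 ± 4.35 FPKM and FOSL1, an AP-1 subunit, from 9.69 ± 0.187 to 35.6 ± 1.11 FPKM. DUSP4 was not called over the 6 libraries, at 2.46 ± 0.251 and 2.82 ± 0.284 FPKM (adjusted p = 0.0783). It was called higher without vehicle replicate 3 (adjusted p = 0.0261) and without halofuginone replicate 2 (adjusted p = 0.0240). Interferon-stimulated genes fell, with 15 of 25 lower, 7 higher and 3 not called (camera adjusted p = 0.0228; adjusted p = 0.402 with an estimated correlation). IFITM1 fell from 11.4 ± 1.06 to 3.17 ± 0.363 FPKM, IFIT1 from 9.70 ± 0.469 to 3.58 ± 0.417 FPKM and IFI44 from 4.57 ± 0.207 to 1.60 ± 0.217 FPKM. B2M was not called, at 816 ± 17.5 and 782 ± 15.7 FPKM. The call of this list ended under quantile normalization (adjusted p = 0.0525) and after median-ratio scaling and removal of trends on GC content and transcript length (adjusted p = 0.187), with medians of -0.40 and -0.30 against -0.34.

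Targets of XBP1 and ATF6, among them the chaperones of the endoplasmic reticulum, were not called as a list, with 16 of 24 higher, 6 lower and 2 not called (camera adjusted p = 0.135). Adjusted over the list alone, 16 were higher and 7 lower. HSPA5, the chaperone BiP, rose 6.47-fold, from 160.4 ± 3.14 to 1038 ± 21.1 FPKM, HERPUD1 from 52.4 ± 1.20 to 164 ± 4.88 FPKM and XBP1 from 32.7 ± 1.245 to 88.7 ± 2.35 FPKM. PDIA3 was not called over the 6 libraries, at 222 ± 8.93 and 210.2 ± 4.04 FPKM (adjusted p = 0.0515). It was called lower without vehicle replicate 2 (adjusted p = 0.0215) and with the replicate number as a block (adjusted p = 0.0375). The same held with a filter at 5 FPKM (0.0494), scaling to the same sum (0.0286), quantile normalization (0.0274) and median-ratio scaling (9.19e-04). Heat shock genes, a list of cytosolic members with the mitochondrial chaperonins HSPD1 and HSPE1 among them, fell. Of 17 tested, 12 were lower, 4 higher and 1 not called (camera adjusted p = 0.00710, and 0.371 with an estimated correlation). HSPA8, the constitutive HSC70, fell 5.49-fold, from 378 ± 11.3 to 68.9 ± 5.60 FPKM, and HSPB1 from 461 ± 47.4 to 185 ± 5.28 FPKM. HSPA1A fell from 8.06 ± 0.235 to 2.88 ± 0.313 FPKM, a level that is uncertain because HSPA1B is a near-identical copy. HSPA4 was not called, at 33.4 ± 0.906 and 34.2 ± 0.460 FPKM.

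Targets of p53 were not called as a list, with 17 of 25 higher and 8 lower (camera adjusted p = 0.135). GADD45A rose from 53.5 ± 2.20 to 283 ± 14.1 FPKM, TNFRSF10B, the death receptor DR5, from 61.6 ± 1.34 to 213 ± 5.87 FPKM and RRM2B, a ribonucleotide reductase subunit, from 18.8 ± 0.841 to 40.1 ± 1.91 FPKM. CDKN1A, the cell cycle inhibitor p21, rose 1.99-fold, from 303 ± 7.82 to 602 ± 24.6 FPKM. Mitotic genes rose, with 25 of 34 higher, 5 lower and 4 not called, and a median log2 change of 0.40 (camera adjusted p = 0.0476; adjusted p = 0.715 with an estimated correlation). HMMR rose from 4.26 ± 0.263 to 16.5 ± 0.980 FPKM and NDC80, a kinetochore protein, from 3.73 ± 0.0381 to 10.8 ± 0.162 FPKM, while KIF20A, a mitotic kinesin, fell from 11.02 ± 0.449 to 4.38 ± 0.149 FPKM. CCNB1, cyclin B1, was not called, at 17.1 ± 0.653 and 18.3 ± 1.03 FPKM, nor was the proliferation marker MKI67, at 3.96 ± 0.142 and 3.74 ± 0.231 FPKM. The call of the mitotic list ended without vehicle replicate 2 (adjusted p = 0.0510), without vehicle replicate 3 (adjusted p = 0.0546) and without halofuginone replicate 1 (adjusted p = 0.0610), with medians of 0.38, 0.41 and 0.42. It also ended with a filter at 5 FPKM (adjusted p = 0.0770, median 0.47) and on transcript rows (adjusted p = 0.0781, median 0.41). After median-ratio scaling and removal of GC content and length trends the median was 0.14 (adjusted p = 0.342). Of 33 DNA replication genes, 14 were higher, 10 lower and 9 not called (camera adjusted p = 0.921), and camera placed the list lower than other genes although its median was 0.04. CDC45 rose from 1.14 ± 0.148 to 5.39 ± 0.430 FPKM, ORC6 from 3.24 ± 0.155 to 10.1 ± 0.366 FPKM and RFC4 from 5.34 ± 0.473 to 12.4 ± 0.592 FPKM. PCNA was not called, at 45.7 ± 1.99 and 44.2 ± 1.03 FPKM.

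Glycolysis enzymes and hypoxia targets fell, with 20 of 25 lower, 4 higher and 1 not called (camera adjusted p = 1.62e-04; adjusted p = 0.371 with an estimated correlation). ALDOC, an aldolase, fell from 8.08 ± 0.309 to 1.08 ± 0.124 FPKM, ANKRD37 from 11.4 ± 0.720 to 3.19 ± 0.388 FPKM and PFKFB4 from 2.95 ± 0.0551 to 0.613 ± 0.0879 FPKM. TPI1 was not called, at 312 ± 10.7 and 319 ± 4.33 FPKM. Nuclear genes of the respiratory chain had 23 of 73 members higher, 33 lower and 17 not called (camera adjusted p = 0.0837). Adjusted over the list alone, 22 were higher and 32 lower. NDUFB9 fell from 68.0 ± 2.92 to 20.1 ± 1.11 FPKM, NDUFS3 from 29.7 ± 1.41 to 14.8 ± 0.818 FPKM and NDUFA2 from 58.4 ± 2.18 to 32.6 ± 2.07 FPKM. COX4I1 was not called over the 6 libraries, at 191 ± 9.69 and 199 ± 4.66 FPKM, and was called higher without vehicle replicate 3 (adjusted p = 0.0302). Of 78 ribosomal protein genes, 16 were higher, 30 lower and 32 not called (camera adjusted p = 0.0586), with a median of -0.03. That median became 0.08 under quantile normalization, -0.10 under median-ratio scaling and -0.16 after median-ratio scaling and removal of GC content and length trends. Adjusted over the list alone, 15 were higher and 29 lower. RPS15 fell from 379 ± 29.2 to 208 ± 10.5 FPKM, RPL7A from 1052 ± 27.1 to 651 ± 20.2 FPKM and RPS3 from 964 ± 44.9 to 646 ± 20.5 FPKM. RPL41 was not called, at 2179.6 ± 78.8 and 2114 ± 30.9 FPKM. Without vehicle replicate 2 both lists were called lower (adjusted p = 0.0485 for the respiratory chain and 0.0286 for ribosomal proteins), and without vehicle replicate 1 the ribosomal list was (adjusted p = 0.0224).

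Translation initiation genes were not called as a list, with 17 of 30 higher, 10 lower and 3 not called (camera adjusted p = 0.502). EIF2S2, a subunit of eIF2, rose from 56.3 ± 2.01 to 188 ± 4.81 FPKM and EIF1 from 251 ± 5.26 to 704 ± 17.4 FPKM, while EEF2K, the kinase of elongation factor eEF2, fell from 5.71 ± 0.146 to 1.78 ± 0.118 FPKM. EIF3B was not called over the 6 libraries, at 41.4 ± 0.576 and 39.3 ± 0.612 FPKM, and was called lower without vehicle replicate 1 (adjusted p = 0.0276). The same held for EIF3B without a filter (0.0311), without variance moderation (0.0181) and with scaling to the same sum (0.0379). It was also called lower under median-ratio scaling (0.00112) and quantile normalization (1.29e-04), but not after median-ratio scaling and removal of GC content and length trends (0.111). Of 33 autophagy and lysosome genes, 18 were higher, 11 lower and 4 not called (camera adjusted p = 0.635). MAP1LC3B, the autophagosome protein LC3B, rose 4.54-fold, from 82.6 ± 3.18 to 375 ± 9.06 FPKM. WIPI1 rose from 36.4 ± 0.793 to 54.7 ± 0.858 FPKM and GLA, a lysosomal galactosidase, fell from 16.1 ± 0.640 to 8.94 ± 0.0965 FPKM. Of 24 cholesterol genes, 8 were higher, 9 lower and 7 not called (camera adjusted p = 0.573), and adjusted over the list alone 8 were higher and 8 lower. The median of this list was 0.02 and its mean -0.07. ACAT2 fell from 6.14 ± 0.107 to 2.49 ± 0.0787 FPKM and EBP from 8.34 ± 0.190 to 4.23 ± 0.347 FPKM. SREBF2 was not called, at 17.4 ± 0.794 and 17.7 ± 0.398 FPKM. Targets of NRF2 had 8 of 21 members higher, 11 lower and 2 not called (camera adjusted p = 0.377), with a median of -0.25 and a mean of 0.02. SRXN1, sulfiredoxin, rose from 26.1 ± 0.682 to 71.4 ± 1.73 FPKM and AKR1B10 fell from 3.20 ± 0.347 to 0.758 ± 0.143 FPKM. TALDO1 was not called over the 6 libraries, at 90.9 ± 3.56 and 94.6 ± 2.89 FPKM, and was called higher without vehicle replicate 3 (adjusted p = 0.0361).

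**Figure D2:**
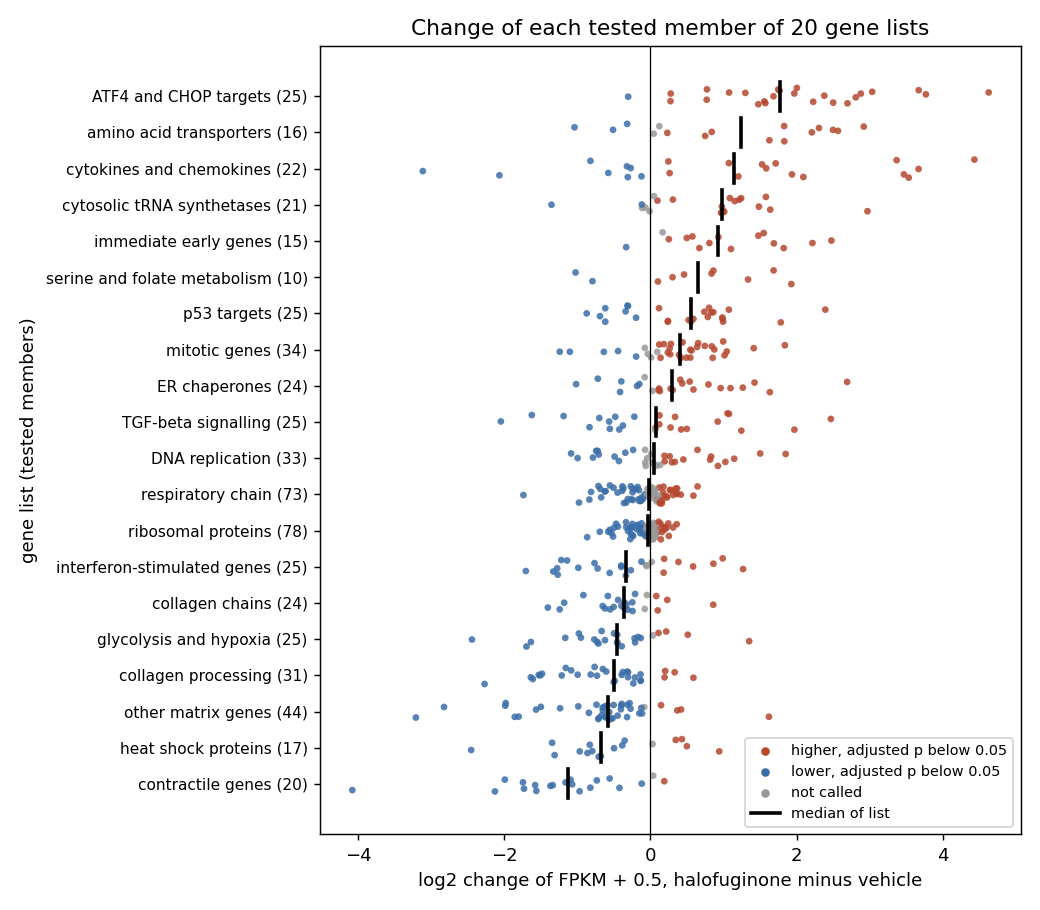
Log2 change of FPKM + 0.5, halofuginone minus vehicle (horizontal axis), of each tested member of 20 of the gene lists (vertical axis, with the number of tested members), in red where called higher, blue where called lower and grey where not called, with a black line at each list's median. The medians run from -1.13 for contractile genes to 1.77 for targets of ATF4 and CHOP.

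Genes that mark cardiac fibroblasts fell, with 14 of 16 lower and 2 higher (camera adjusted p = 1.12e-04; adjusted p = 0.354 with an estimated correlation). Smooth muscle and pericyte genes had 8 of 8 members lower (camera adjusted p = 1.85e-04; adjusted p = 0.246 with an estimated correlation), and 6 of 7 mesothelial and epicardial genes were lower and 1 higher (camera adjusted p = 0.0116; adjusted p = 0.246 with an estimated correlation). These falls are in part those given above: 5 of the fibroblast genes (COL1A1, COL1A2, COL3A1, DCN and LUM) are also in the matrix lists, and 3 of the smooth muscle genes (LMOD1, CNN1 and ACTG2) in the contractile list. Of 7 endothelial genes tested, 3 were higher and 4 lower (camera adjusted p = 0.559). Of 3 epithelial genes 3 were lower (camera adjusted p = 0.135), and of 3 Schwann cell and neuronal genes 2 were higher and 1 lower (camera adjusted p = 0.921). Both tested cardiomyocyte genes, TNNT2 and NPPB, were lower, from 5.51 ± 0.405 to 2.92 ± 0.292 and from 159 ± 4.25 to 126 ± 6.79 FPKM. Both tested leukocyte genes, CD14 and CD68, were lower, CD68 from 27.5 ± 2.09 to 18.7 ± 0.880 FPKM. Of the 2 tested adipocyte genes, FABP4 fell from 8.43 ± 1.09 to 1.08 ± 0.197 FPKM and PPARG rose from 2.35 ± 0.172 to 3.81 ± 0.296 FPKM. No erythroid gene reached the filter. These genes, apart from CD14, lie outside the rule for named genes and were chosen after their values were seen, because their lists had 2 tested members. Replication-dependent histone genes, whose mRNA normally has no poly(A) tail, rose, with 7 of 9 higher and 2 not called (camera adjusted p = 0.0228; adjusted p = 0.419 with an estimated correlation).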

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

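The tests on transcript rows, against a 2-fold change and with GC content and length trends removed after median-ratio scaling (2 changes at once, below called trend removal) were chosen after the data were seen. The counts of genes higher, lower and changed at least 2-fold stayed within 1.5 times their main values under the settings tried, with 2 exceptions. With a filter at 5 FPKM, 497 genes were lower by at least 2-fold against 823, since fewer genes were tested, and the treat test called 646 genes higher by over 2-fold against 977, since it asks for more than a 2-fold change. The balance of 2-fold changes turned to 825 higher and 948 lower under median-ratio scaling, 818 and 955 under quantile normalization and 711 and 809 after trend removal. Leaving out 1 library gave 5453 to 5708 genes higher, 4002 to 4188 lower, 1768 to 1862 changed at least 2-fold and 15 to 17 lists. Of the 9842 called genes, 9313 were called in the same direction under median-ratio scaling and 9104 under quantile normalization. After trend removal, 7992 of the 9460 that could be tested were, and 1292 of 1716 stayed changed at least 2-fold. The median log2 change of tested genes was 0.10, and 0.03 and 0.02 under these scalings. The number of lists called went from 16 to 0 with an estimated correlation and to 33 with fry.

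Among 128 named genes and 34 lists, those that turned direction were not called in the main test, and the cause was not tested. Under median-ratio scaling the log2 change became -0.0265 for KARS, -0.0255 for SLC7A6, -0.0549 for PLAUR, -0.0373 for TPM1, -0.00780 for SKI, -0.0435 for HSPA4, -0.0479 for SREBF2, -0.0189 for COX4I1, -0.0177 for TALDO1 and -0.0401 for TPI1. Under quantile normalization it became -0.0718 for KARS, -0.0499 for CARS2, -0.0695 for SLC7A6, -0.12 for PLAUR, -0.0729 for SKI, -0.0297 for CCNB1, -0.10 for HSPA4, -0.10 for SREBF2, 0.22 for RPL41, -0.0420 for TALDO1 and 0.11 for B2M. B2M and RPL41 were called higher there (adjusted p = 9.59e-04 and 6.08e-07) but lower under median-ratio scaling (-0.14 and -0.12, adjusted p = 7.41e-04 and 0.00286), so their direction rests on the scaling. TPM1 was called higher under quantile normalization (0.17, adjusted p = 3.83e-04). KARS, PLAUR and HSPA4 were called lower there (adjusted p = 0.0479, 0.0218 and 0.0276). On transcript rows the log2 change was -0.0494 for KARS and 0.0716 for PCNA. After trend removal it was -0.14 for KARS, -0.0644 for SLC7A6, -0.13 for TPM1, -0.18 for CCNB1, -0.19 for HSPA4 and 0.0601 for EIF3B. Of these, KARS, TPM1, CCNB1 and HSPA4 were called lower (adjusted p = 0.00153, 8.03e-04, 0.00412 and 3.06e-04). Leaving out 1 library gave -0.00458 to 0.0540 for PLAUR, below 0 without vehicle replicate 1 or halofuginone replicate 3, and -0.0120 to 0.0447 for SREBF2, below 0 without vehicle replicate 1.

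Lists that camera placed on the other side of the remaining genes had these medians. Without a filter the median was 0.0703 for TGF-beta signalling, 0.0447 for replication and -0.0177 for Schwann cell and neuronal genes. For proline, asparagine, glutamate and glutamine metabolism it was -0.0666 with a filter at 5 FPKM, -0.14 under median-ratio scaling, -0.20 under quantile normalization and -0.0814 to -0.0422 with 1 library left out (turned without vehicle replicate 2). Under quantile normalization it was 0.0384 for replication and 0.0789 for ribosomal proteins, and after trend removal 0.0201 for TGF-beta signalling. Fry, which tests against no change, gave the direction higher for TGF-beta signalling (median 0.0703), replication (0.0447) and, without a call, NRF2 targets (-0.25, FDR 0.0526). Lists not called in the main test became called under some settings. Beside serine synthesis these were ribosomal proteins and the respiratory chain, lower under median-ratio scaling (adjusted p = 0.00289 and 0.0201), and without a filter cytokines (0.0196), p53 targets (0.0469) and matrix metalloproteinases (0.0295). Of 21 named genes not called in the main test, 8 were called lower under median-ratio scaling, under quantile normalization 3 higher and 8 lower, and after trend removal 8 higher and 10 lower. MKI67 was among those under median-ratio scaling (log2 change -0.14, adjusted p = 0.0473).

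The replicate numbers were not taken as pairs. Deviations of same-numbered libraries from their group means correlated at 0.09, -0.06 and 0.13. With the replicate block, 5689 genes were higher, 4215 lower and 1801 changed at least 2-fold, and 16 lists were called. Depth limits low genes: at 1 FPKM, a 2 kb transcript had 52 reads in the shallowest library.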

Other observations

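The gene families and transcripts in this part and the scaling of the mitotic list were chosen after the results were seen. So were the tests of abundant transcripts, of the cell cycle as a whole and of GC bias. The bounds of the last 2 were set with their values known. Tests of the other splits, of GC content on the mitotic list and of proline content were written after the main result was seen and before their own values were known. Of 139 families of genes sharing a symbol stem with at least 10 tested members, aldehyde dehydrogenases (ALDH) had 13 of 15 members lower and 2 higher (camera adjusted p = 0.0104), with a median log2 change of -0.72. Semaphorins (SEMA), guidance proteins, had 9 of 12 lower, 5 of them by at least 2-fold, and 1 higher (camera adjusted p = 0.0240). Genes with the stem CDC, many of them of the cell cycle, had 25 of 27 higher and 1 lower (camera adjusted p = 0.00466), and histone genes (HIST) 17 of 20 higher and 1 lower (camera adjusted p = 0.0321). Collagens (COL) had 18 of 25 lower and 5 higher (camera adjusted p = 0.0106). Each of these families had an adjusted p = 0.942 with an estimated correlation. The COL, CDC and HIST families share members with the collagen, mitotic, replication and histone lists above, so they are in part the same results.

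Among 465 genes with 2 or more transcripts of at least 10 FPKM, 7 had transcripts whose log2 changes lay at least 4-fold apart. For TSC22D1, NM_006022 went from 31.2 ± 0.526 to 140.6 ± 9.85 FPKM and NM_183422 from 47.3 ± 1.07 to 25.1 ± 0.996 FPKM (n = 3 libraries per group). For SAT1, a polyamine acetyltransferase, the non-coding NR_027783 went from 47.0 ± 3.44 to 208 ± 11.8 FPKM and the coding NM_002970 from 500.04 ± 11.2 to 289 ± 12.9 FPKM. The fall of ACTA2 was that of NM_001613, from 189 ± 6.25 to 27.8 ± 1.48 FPKM, while NM_001141945 went from 22.4 ± 0.469 to 20.2 ± 0.117 FPKM. TPM1, outside these 7 with a gap of 1.89 on the log2 scale and not called as a sum, had NM_001018006 higher, from 253.7 ± 8.22 to 396 ± 12.01 FPKM, and NM_001018007 lower, from 44.0 ± 3.49 to 18.2 ± 1.08 FPKM. Levels of single transcripts rest on how the authors' program split shared reads, which was not tested.

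The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only the real split, 1 of 10, gave 5664 genes higher and 4178 lower, and the highest of the other splits was 0 with limma. Those splits had 3 to 14 genes at an unadjusted p below 0.05, against 9912 in the real split. Each of the other splits mixes vehicle and halofuginone libraries. The treatment difference then widens the spread within its groups and keeps its gene counts low, so they do not show what chance gives. For genes changed at least 2-fold the real count was 1800 and the highest other 0, again 1 of 10. For gene lists the real count was 16 and the highest other 14 (1 of 10), where the other splits still hold part of the treatment difference.

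More genes were called higher than lower, 57.5% of those called. A candidate explanation is the per-million scale of FPKM: the 50 most abundant genes took 23.1% ± 0.21 of the estimated reads in vehicle and 18.4% ± 0.25 in halofuginone (SD, n = 3), which alone raises the others by 0.086 on the log2 scale. The shift was 0.060 from the 20 and 0.043 from the 10 most abundant genes, the last below 0.5 of the median change of 0.10, so the part this explains depends on how many genes are counted. Under median-ratio scaling 52.3% of called genes were higher, but genes changed at least 2-fold were more often lower (825 higher and 948 lower, against 977 and 823). Whether halofuginone moved more genes in one direction stays open.

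Mitotic genes were higher while CDKN1A rose. Library scaling moves the genes of a library alike, so the result under median-ratio scaling follows from the size of the scaling and is no separate test. The median of all genes went from 0.10 to 0.03 and that of the list from 0.40 to 0.34, so this scaling left most of the list's rise. GC content and length could account for most of it: the excess of the list's median over other genes went from 0.31 (quartiles 0.00 and 0.62) to 0.10 (quartiles -0.17 and 0.52) when these trends were removed after median-ratio scaling, and camera did not call the list then (adjusted p = 0.342). Whether more cells were in cycle as a whole stays open, since the mitotic list lay above the replication list by a mean of 0.24 with a permutation p = 0.15 (100000 resamples), and the replication list was not called. The GC trend may itself be part of the response, so the list is not shown to be an artifact.

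Transcripts of low GC content were higher: over 4 equal groups of genes in order of rising GC content the median log2 change was 0.36, 0.18, 0.02 and -0.16 (Spearman's rho = -0.309 across 11237 genes, which are not independent replicates). A GC bias varying from library to library was examined with a bound set after its values were known. Over 9 pairs, libraries of different groups differed in slope on GC content by 0.152 to 0.289 per 10 percentage points. Pairs of one group reached at most 0.0999, below the smallest of these by more than the SD of 0.0402 within groups. The 9 pairs share the same 6 libraries, and with 3 libraries against 3 no exact test can give a p below 0.1. Such a bias is therefore not excluded, as the whole cause or as a part of it. A bias shared by one group's libraries cannot be told apart from halofuginone, because no batch in the labels crosses the groups, and the slope between the groups was -0.2349. One hypothesis was that transcripts of proline-rich proteins fell because the drug blocks prolyl-tRNA synthesis. The rho with proline content was -0.167 across 10841 genes without the collagens. It was -0.0234 once coding GC content and protein length were removed, which argues against proline content beyond its link with GC content. Proline codons are rich in G and C, so this removal may also take out part of an effect of proline itself.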
